A study of Papaver somniferum with 9 samples.

How the data were processed

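Poly(A) RNA from pooled tissue of 9 samples was sequenced after a strand-marking library preparation, per the labels' protocols, from 100 mg of ground tissue and 400 ng of total RNA. The submitters' processing notes name FastQC, Trimmomatic 0.32, HISAT2 2.1.0 and StringTie 1.3.3. Per the file headers, StringTie ran in the mode that estimates a given set of models, on models merged over all 9 samples. The genome build and the strand setting of the alignment are not given in the sources used here. Coordinates are those of the files, and values of overlapping or antisense genes and of near-identical copies are uncertain.

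The authors deposited a table of FPKM (fragments per kilobase of model per M mapped fragments) for 51209 genes and, per library, a file of all models with their coverage, FPKM and TPM; the attribute column of those deposited files was read for these other values. The files hold 174168 models: 49415 named as mRNA, 48385 that cover a gene from end to end as 1 exon, and 76368 assembled from the reads. Each cell of the table equals the highest FPKM among the annotated models of its gene, in 460881 of 460881 cells within 2e-06 FPKM, so reads that StringTie gave to an assembled model at the same place are not in it. The table held 45.8% to 54.2% of the FPKM of a library. For genes with several exons and at least 5 FPKM, 3.95% to 5.77% of the values came from the end-to-end model, which includes introns.

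Depth was recovered from the files. FPKM is coverage divided by the total of aligned bases, so the median of their ratio gave that total, 3.22 to 13.9 Gb. The most frequent low base total of a 1-exon model was 302, which was taken as the bases of 1 fragment. Fragments of a model were its coverage times its length divided by 302. Where both values came from the same model, 95% intervals of a ratio were exact conditional (Clopper-Pearson) intervals. Where a library had no fragment, the bound used a floor of 3 fragments per library, which for a model of 1 kb is 0.0653 to 0.281 FPKM. Intervals and floors cover counting error only, and not the spread between plants or pools. They also take no account of the choice of genes with the most extreme ratios.

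Each group was 1 library, so no test between groups was run. The comparisons were fixed before the data were examined: the 7 tissues of day 1, day 5 against day 1 in stem and in capsule, capsule against stem on each day, fine root against tap root, and stamen against petal. Ratios are log2 of (FPKM + 1) in both libraries, which understates differences of low genes. Genes with at least 5 FPKM in either library were measured, and 2-fold counted as higher or lower. A class median was placed among 10000 random lists of the same size drawn from 20 bins of mean log2 expression, as a description of these libraries.

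The 34 functional gene lists and the coexpression of alkaloid genes fixed beforehand were not used, because no gene had a name. None of the gene identifiers (0 of 51209) matched the 91581 genes of the name table for assembly ASM357369v1. The plan also allowed names by overlap of exons if the assembly was the same, but no name was taken that way. The rule for named genes then allowed at most 2 identifiers higher and 2 lower per comparison, those with the most extreme log2 ratio among genes with at least 10 FPKM in either library. The rule gave no such number for single tissues, where 2 genes with at least 50 FPKM were named. Classes of tissue-enriched genes, defined without the compared tissues, took the place of the lists; this was decided after the data were examined. Medians were computed for classes of at least 20 measured genes. For each named gene, the sum of FPKM over all models of its StringTie locus is given where it changes the picture; a locus can hold more than 1 gene.

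Alternatives fixed beforehand were a pseudocount of 0.1 or 5, a minimum of 1 or 20 FPKM, TPM, median-of-ratios factors over the 1241 genes with at least 5 FPKM in every library, leaving out the 100 most abundant genes, and a 4-fold rule. The mRNA model alone and the locus total were added after the data were examined. The code was tested on simulated data before use: with counts drawn at the real depths, 200 of 200 genes changed 4-fold were called in each of the 6 comparisons, and counting noise called at most 0.04% of 6968 unchanged genes, in the stem comparison. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.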

Results

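The data were messenger RNA profiles of opium poppy, Papaver somniferum, cultivar High Noscapine 1 (HN1), a line named for its content of the benzylisoquinoline alkaloid noscapine. The 9 libraries were each made from pooled tissue, with 1 library per group. On day 1 of anthesis, the opening of the flower, 7 tissues were taken: stem, leaf, capsule, petal, stamen, tap root and fine root. The stem sample was a 2 cm piece directly under the capsule. Stem and capsule were taken again on day 5 from other plants, which had been hand-pollinated on day 1 and had dropped their petals. No group had a replicate, so no difference below has a replicate check or a p-value, and "higher" and "lower" describe these libraries. The genes are named by the identifiers of the deposited files, which do not pair them with gene names or functions.

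The depth recovered from the files ran from 10.7 M fragments in day 1 stem to 45.9 M in stamen, a 4.30-fold range. The others had 12.3 M (day 1 capsule), 13.2 M (day 5 capsule), 21.1 M (day 5 stem), 23.8 M (tap root), 29.9 M (petal), 42.8 M (leaf) and 45.8 M (fine root). Of 51209 genes, 13983 reached 5 FPKM in at least 1 library and 1241 did so in every library. Fine root had the most genes at 1 FPKM or more, 15406, and stamen the fewest, 7411, although stamen was the deepest library. In stamen the 10 most abundant genes held 16.8% of the summed FPKM of the gene table, against 3.72% in fine root.

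The first question was which genes set each tissue apart on day 1. Fine root had 583 tissue-enriched genes, the largest set with FPKM as deposited, where enriched means at least 5 FPKM and, with 1 FPKM added, at least 5 times the value of every other tissue. Leaf had 310 such genes, capsule 287, petal 129, stem 106, tap root 83 and stamen 75. This order depended on the scaling: with median-of-ratios factors, which raise the values of stamen, stamen had the largest set, 582 genes, and fine root had 456. Of the summed FPKM of the gene table, which leaves out assembled models, the 310 leaf genes held 13.5% in leaf and the 583 fine root genes 9.91% in fine root. On the same basis, petal genes held 7.09% in petal, stem genes 5.17% in stem, tap root genes 4.27% in tap root, capsule genes 4.11% in capsule and stamen genes 2.62% in stamen.

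For each tissue, the 2 enriched genes with the largest ratio to the second highest day 1 tissue are named. In stem these were PS033659.1 (chromosome 3, 211801592 to 211802032, plus strand, 1 exon) at 900.5 FPKM and PS073102.1 (chromosome 7, 194521457 to 194521897, plus strand, 1 exon) at 689 FPKM, against 1.14 and 2.02 FPKM in the next tissue. The ratio was 787 for PS033659.1 (95% counting interval 449.6 to 1523) and 341 for PS073102.1 (189.7 to 682). The leaf genes were PS011143.1 (chromosome 1, 54092919 to 54093911, minus strand) at 105 FPKM and PS011239.1 (chromosome 1, 58585505 to 58587175, minus strand) at 149 FPKM, with next values of 0.235 and 1.20 FPKM. In capsule, PS101334.1 (chromosome 10, 84641309 to 84642613, plus strand) had 194 FPKM against 0.215 in stem, and PS090997.1 (chromosome 9, 37588960 to 37590476, minus strand) had 134 FPKM against 0.0727 in tap root.

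In petal, PS053498.1 (chromosome 5, 187081083 to 187086309, minus strand, 10 exons) had 63.4 FPKM against 0.655 in leaf, a ratio of 96.8 (76.2 to 126), and PS020496.1 (chromosome 2, 22764744 to 22765202, plus strand) had 217 against 5.37 in capsule. The stamen genes were PS090863.1 (chromosome 9, 31437981 to 31442557, plus strand, 4 exons) at 583 FPKM and PS111313.1 (chromosome 11, 61860569 to 61861564, minus strand) at 152 FPKM, with next values of 0.152 and 0.161 FPKM. The values of PS111313.1, and those of the petal gene PS020496.1, came from the end-to-end model. For PS090863.1 the total over all models of its locus was 815 FPKM in stamen, 296 in petal and 79.9 in fine root, so most of its 3833-fold difference was not found at the level of the locus. The tap root genes were PS040956.1 (chromosome 4, 43744034 to 43744810, minus strand) at 340.2 FPKM against 1.70 in capsule, and PS093390.1 (chromosome 9, 175849574 to 175850536, plus strand) at 88.1 FPKM against 1.37 in stem. Both were also present in day 5 stem, PS040956.1 at 511 FPKM, above its tap root value, and PS093390.1 at 37.1 FPKM, and PS040956.1 had 33.5 FPKM in day 5 capsule. In fine root, PS090835.1 (chromosome 9, 30470128 to 30471243, minus strand) had 98.1 FPKM and PSUN1700.1 (unplaced scaffold 117, 5931865 to 5932080, minus strand) had 102 FPKM, against 0.492 and 1.22 in tap root.

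Among the 13983 genes at 5 FPKM or more in some library, petal and stamen had the highest rank correlation of any pair (Spearman's rho 0.804 across genes, which are not independent replicates). The 2 ages of capsule gave 0.794, the 2 ages of stem 0.789, and tap root with fine root 0.742. Day 5 stem was closer in rank to leaf (0.707) and to tap root (0.688) than day 1 stem was (0.637 and 0.590), and farther from day 1 capsule (0.654 against 0.760). Over all 51209 genes the 2 ages of stem correlated most highly (0.853), and petal with stamen gave 0.790.

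**Figure D1:**
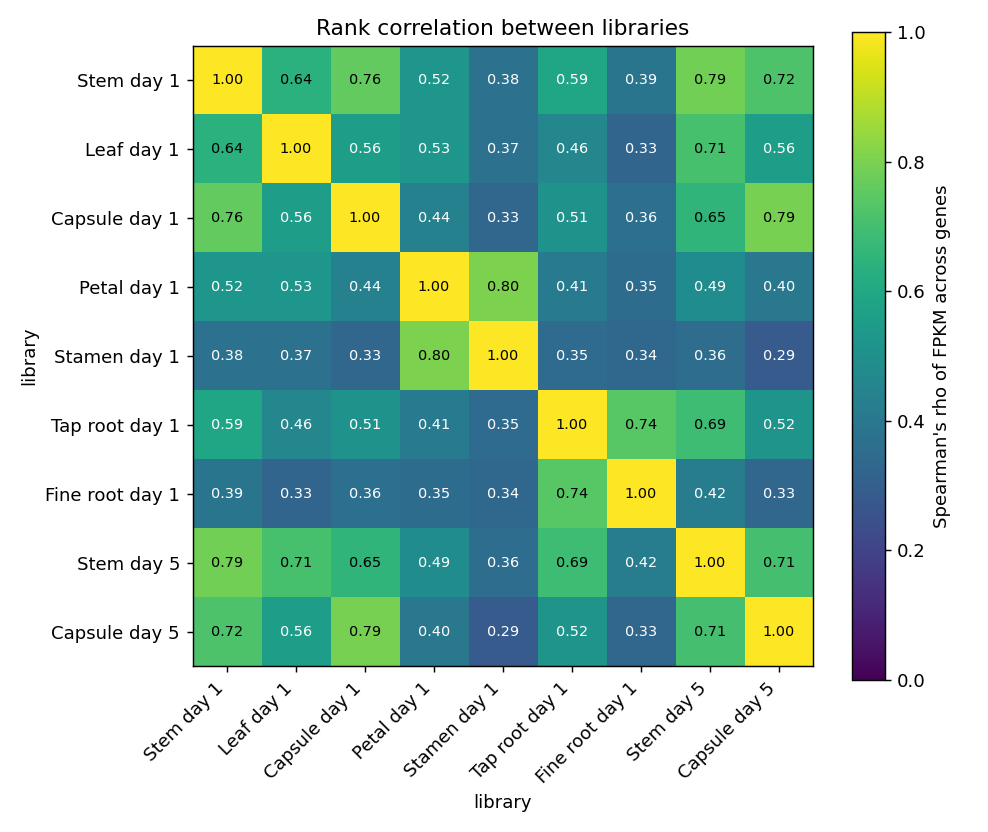
Spearman's rho of FPKM between each pair of the 9 libraries (rows and columns), across the 13983 genes with at least 5 FPKM in some library. Petal with stamen (0.804), the 2 ages of capsule (0.794) and the 2 ages of stem (0.789) stand highest, and stamen with day 5 capsule (0.287) lowest.

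The next question was how stem differed between day 5 after pollination and day 1. Among the class members measured in stem (at least 5 FPKM in either library), most tap root genes were higher at day 5 and most capsule genes were lower. For this and the following comparisons, classes were defined without the compared tissues, and they were chosen after the data were examined. Of 141 tap root genes 108 were measured, and 72 of these were at least 2-fold higher at day 5 and 12 lower, with a median log2 ratio of 1.60. Of 385 capsule genes only 96 were measured, of which 7 were higher and 74 lower (median -2.75, or -1.48 with a minimum of 1 FPKM, -3.49 with a minimum of 20 FPKM and -2.15 with a pseudocount of 5). Of 162 petal genes 87 were measured, with 12 higher, 44 lower and 31 neither (median -1.06, or -2.86 with a minimum of 20 FPKM). Leaf genes were split 77 higher to 36 lower among 250 (median 0.46), and of 600 fine root genes only 27 were measured, with 17 higher and 8 lower (median 1.92, or 0.82 with a minimum of 1 FPKM). The tap root, leaf and fine root medians lay above all of 10000 random lists matched on expression, and the capsule and petal medians below all of them.

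PS011389.1 (chromosome 1, 64781821 to 64784475, plus strand, 2 exons) had 502 FPKM in day 5 stem and 0.279 in day 1 stem, a ratio of 1800.1 (871 to 4465), with 194 FPKM in tap root. PSUN8718.1 (unplaced scaffold 80, 2606345 to 2606867, minus strand) was listed at 1218 and 1.93 FPKM, but its locus total was 2423 against 764 FPKM, a ratio of 3.17. PS030689.1 (chromosome 3, 28959429 to 28962363, minus strand, 3 exons) was lower, 0.626 against 842 FPKM, or 1346-fold (901 to 2134). PS042533.1 (chromosome 4, 144547715 to 144549816, minus strand, 5 exons) was lower as well, 0.877 against 835 FPKM, or 953-fold (669.8 to 1383). Both were also abundant in petal, at 422 and 2446 FPKM. In all, 8500 genes had at least 5 FPKM in either stem library, and of these 1341 (15.8%) were at least 2-fold higher at day 5 and 1640 (19.3%) lower. More genes were higher than lower with TPM (2024 and 1941 of 10955 measured) and without the 100 most abundant genes (1740 and 1432 of 8976), but not with median-of-ratios factors (1353 and 1466 of 8076). Age, pollination and the set of plants differed together between the 2 libraries.

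Capsule was compared between the same days. Of 92 tap root genes 38 were measured, with 21 higher at day 5 and 2 lower and a median log2 ratio of 1.16. Of 620 fine root genes 41 were measured and split 20 higher to 12 lower (median 0.92, or 1.54 in the locus total), and leaf genes 38 to 27 among 151 (median 0.20). All 3 medians lay above all 10000 random lists, while those of stem genes (32 higher and 54 lower of 141, median -0.31) and petal genes (14 higher and 19 lower of 64, median -0.09) lay at the 9.82 and 86.4 percentile.

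PSUN3110.1 (unplaced scaffold 132, 8589015 to 8589938, plus strand) had 1487 FPKM in day 5 capsule against 0.672 at day 1, a ratio of 2212 (1073 to 4900). PS020354.1 (chromosome 2, 15539036 to 15539956, plus strand) had 1388 FPKM at day 5 and no fragment at day 1, so it was at least 5248-fold higher against a floor of 3 fragments. Both were at most 0.672 FPKM in all 7 day 1 tissues and reached 8.86 and 18.5 FPKM in day 5 stem. PS101334.1, the capsule gene named above, was lower at day 5, 0.254 against 194 FPKM, or 763-fold (327 to 3074). PS020281.1 (chromosome 2, 12334277 to 12334468, plus strand) was listed at 0.132 against 116 FPKM, yet its locus total was 99.6 against 147 FPKM, which is under 2-fold. Of 9213 genes measured, 1245 (13.5%) were higher at day 5 and 1801 (19.5%) lower. With TPM these were 1488 and 2930 of 11756, and with median-of-ratios factors 1200 and 1705 of 8882.

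Stem and capsule shared part of their day 5 differences. Among 7131 genes measured in both, 322 were higher at day 5 in both tissues, where independent lists would share 96.4, and 451 were lower in both, where independent lists would share 212. In opposite directions, 87 genes were higher in stem and lower in capsule (140.4 for independent lists) and 124 lower in stem and higher in capsule (145.6). The log2 ratios of the 2 tissues correlated across genes with Pearson's r of 0.299 and Spearman's rho of 0.318. The 2 comparisons share no library, but both set other, hand-pollinated plants on day 5 against the plants of day 1. A difference between the sets of plants would count in both, so the shared part cannot be assigned to age or pollination.

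**Figure D2:**
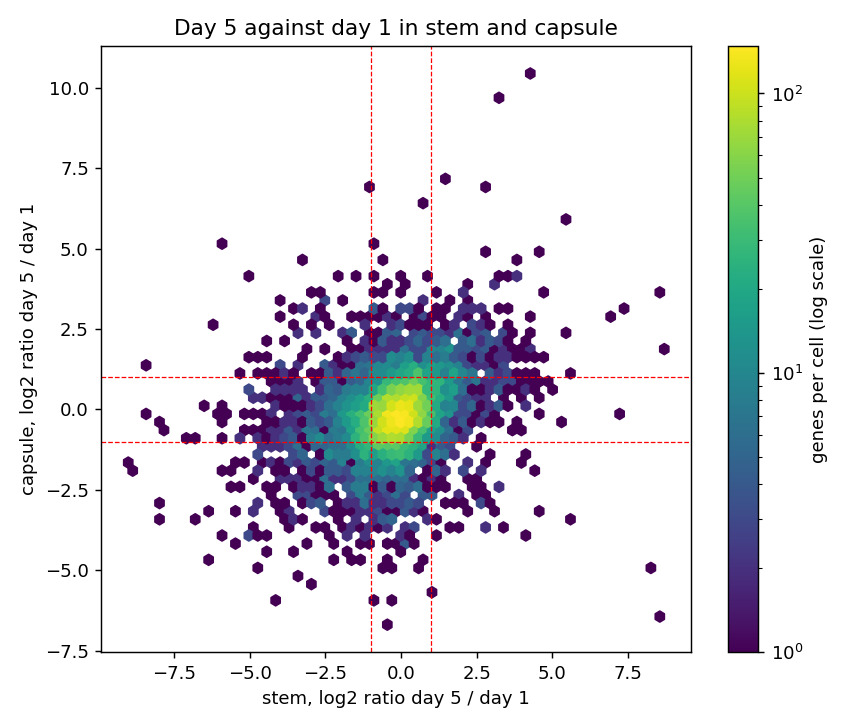
Log2 ratio of day 5 to day 1 (FPKM + 1) in stem (x axis) and capsule (y axis) for the 7131 genes measured in both, as hexagons shaded by the number of genes on a log scale; dashed lines mark 2-fold. The upper right and lower left corners hold 322 and 451 genes, the lower right and upper left corners 87 and 124.

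Capsule was also set against the stem directly beneath it. Of 192 tap root genes, 117 were measured at day 1, where 8 were higher in capsule and 80 lower (median log2 ratio -2.12, or -1.19 with a minimum of 1 FPKM, -1.37 with TPM, -1.42 with a pseudocount of 5 and -1.45 without the 100 most abundant genes). At day 5, 145 were measured, and 9 were higher and 104 lower (median -2.09). Of 650 fine root genes only 46 were measured at day 1 and 60 at day 5. At day 1, 24 of these were higher in capsule and 11 lower (median 1.23, or 0.34 in the locus total), and at day 5 32 were higher and 18 lower (median 2.28, or 0.64 with a pseudocount of 5, 0.79 with a minimum of 1 FPKM and 1.41 with TPM). Petal genes were split 24 higher, 52 lower and 57 neither at day 1 (median -0.60) and 39 higher, 23 lower and 42 neither at day 5 (median 0.52). Leaf genes were split 65 higher to 106 lower among 601 at day 1 (median -0.11) and 88 to 143 among 630 at day 5 (median -0.24). Each of these medians lay outside the middle 95% of matched random lists.

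At day 1, PS092215.1 (chromosome 9, 105387992 to 105390131, plus strand, 4 exons) had 284 FPKM in capsule and 0.197 in stem, and PS101334.1 had 194 and 0.215 FPKM, a ratio of 904 (308 to 4369). The stem genes PS033659.1 and PS073102.1 were lowest relative to stem. PS033659.1 had no fragment in capsule and was at least 1630-fold lower there, and PS073102.1 was 341-fold lower (189.7 to 682). At day 5, PS053110.1 (chromosome 5, 173576483 to 173577455, minus strand) had 966 FPKM in capsule against 0.534 in stem, a ratio of 1809 (942 to 3912). PS052072.1 (chromosome 5, 132978937 to 132979326, plus strand) had 307 against 0.121 FPKM, which is about 1 fragment in stem, so its ratio of 2534 has an interval of 453 to 99820. Both had been present in day 1 stem, at 57.5 and 271.5 FPKM. PSUN0144.1 (unplaced scaffold 10, 3657242 to 3659630, plus strand) was lower in capsule, 0.696 against 1473 FPKM, and in its locus total 20.6-fold lower. PSUN8718.1 was listed as 345.5-fold lower in capsule at day 5, but its locus total was 2.29-fold lower. At day 1, 1875 of 9205 genes were higher in capsule and 1425 lower, but 641 higher and 712 lower of 3434 with a minimum of 20 FPKM. At day 5, 1849 of 8913 were higher and 1714 lower, but 2189 higher and 2600 lower of 11377 with TPM.

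The root samples were compared on day 1. Stem genes were lower in fine root than in tap root, with 19 higher and 97 lower of 141 and a median log2 ratio of -1.89. Of 165 leaf genes, 81 were higher, 26 lower and 58 neither (median 0.97). Capsule genes were split 29 higher, 14 lower and 21 neither (median 0.88) and petal genes 28 higher, 8 lower and 34 neither (median 0.64). Of 93 stamen genes only 28 were measured, with 19 higher and 2 lower (median 1.78, or 2.55 with median-of-ratios factors). The median of all 9353 genes was 0.31, and each class median lay outside the middle 95% of its random lists. PS040956.1 had 340.2 FPKM in tap root and 0.146 in fine root, 2328-fold lower (1037 to 7461); its value came from the end-to-end model, and its mRNA model had no reads in either root. PS092629.1 (chromosome 9, 126012618 to 126016059, plus strand, 7 exons) had 299 and 1.49 FPKM, 201-fold lower (174 to 235). Both were also high in day 5 stem, at 511 and 273 FPKM. PS090835.1 was higher in fine root, 98.1 against 0.492 FPKM. PS091014.1 (chromosome 9, 38134070 to 38136430, minus strand) was listed at 63.9 against 0.0310 FPKM, but its locus total was 611 against 484 FPKM, a ratio of 1.26, and its mRNA model gave a log2 ratio of 0.00. Of the 9353 genes, 2410 (25.8%) were higher in fine root and 1065 (11.4%) lower. The imbalance was smaller under other scalings. Higher and lower were 2992 and 1705 with TPM, 1905 and 1234 with median-of-ratios factors, and 2200 and 1501 without the 100 most abundant genes.

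In the flower, stamen was compared with petal. Most measured stem, leaf and capsule genes were lower in stamen: 47 of 58 stem genes (median log2 ratio -3.27), 98 of 134 leaf genes (median -2.40) and 28 of 35 capsule genes (median -2.47), with 6, 7 and 5 higher. The classes held 153, 407 and 324 genes, and with a minimum of 1 FPKM all 3 medians were nearer to 0 (-1.76 for leaf genes and -1.45 for capsule genes). The stem median was -3.94 with a minimum of 20 FPKM, the leaf median -1.42 with a pseudocount of 5 and the capsule median -3.69 with a pseudocount of 0.1. Of 637 fine root genes only 45 were measured, with 32 higher in stamen and 8 lower (median 1.59), above all 10000 random lists. PS063011.1 (chromosome 6, 136852556 to 136854128, minus strand) had 307.5 FPKM in stamen and 0.749 in petal, a ratio of 411 (297 to 594) that came from its end-to-end model, since with the mRNA model alone its log2 ratio was 0.10, and PS090863.1 was described above. PS071022.1 (chromosome 7, 41523836 to 41525557, plus strand) was lower in stamen, 0.188 against 305 FPKM, or 1624-fold (974 to 2872). PS051793.1 (chromosome 5, 118540438 to 118540710, minus strand) was lower as well, 0.409 against 328 FPKM, or 802-fold (352 to 2535).

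Of 5753 genes measured in petal or stamen, 1124 (19.5%) were higher in stamen and 3237 (56.3%) lower, with a median of -1.33 over all of them. This split depended on the scaling. Median-of-ratios factors raise every stamen to petal log2 ratio by 0.89 before 1 FPKM is added, and by less after. With them, 1986 genes were higher and 2289 lower, and the share of higher among called genes was 46.5%, against 25.8% with FPKM as deposited. The class medians of the leaf and capsule genes were then -1.76 and -1.58.

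**Figure D3:**
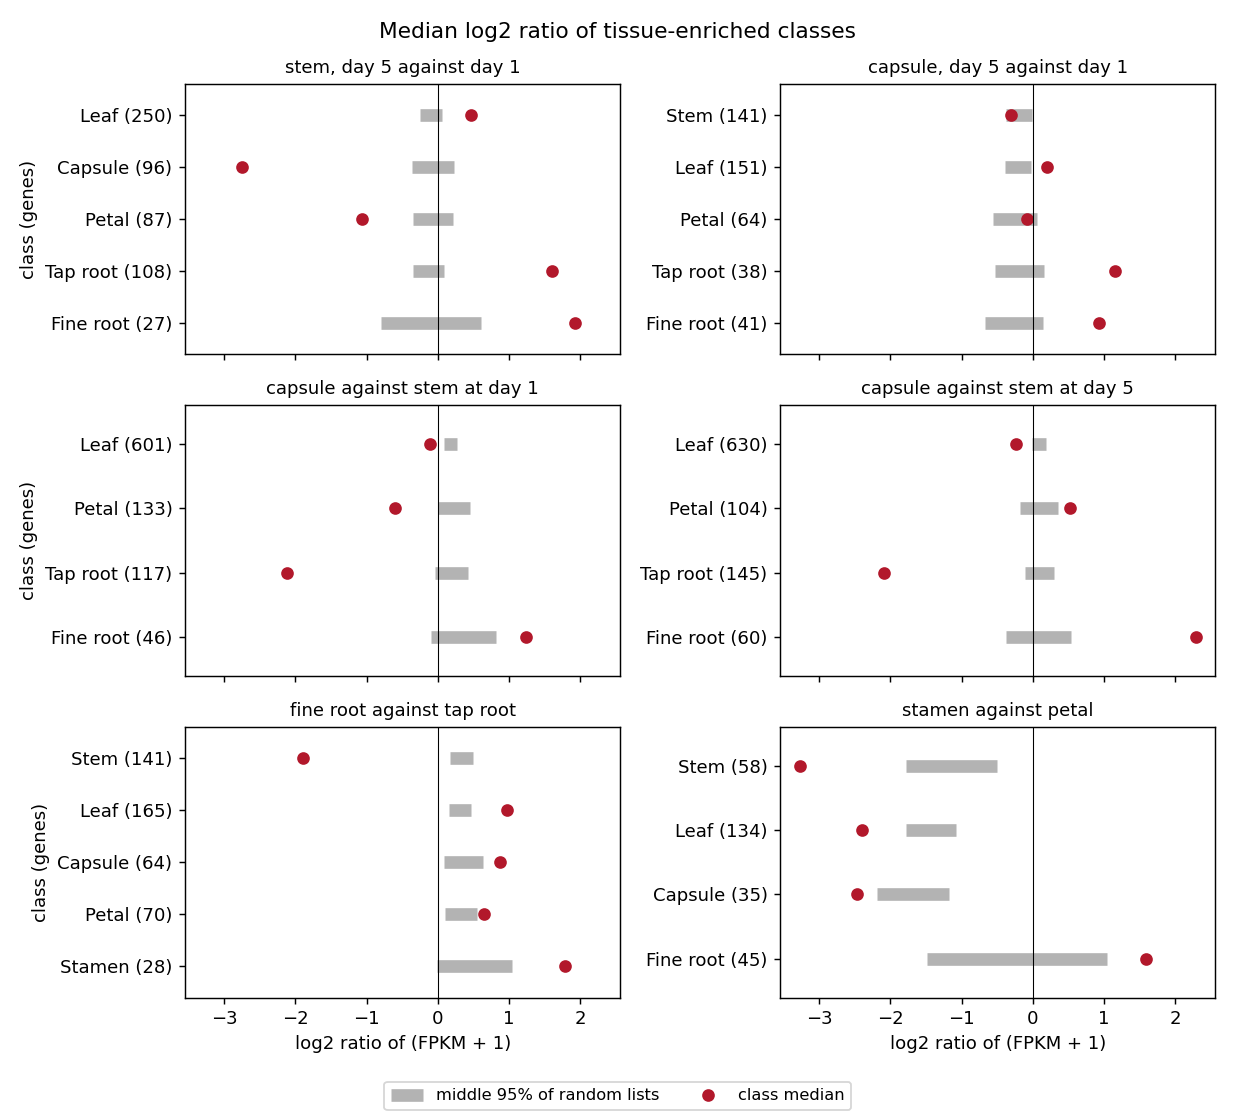
Median log2 ratio of (FPKM + 1) of the measured genes of each tissue-enriched class (points; y axis, with the number measured) in the 6 comparisons, beside the middle 95% of 10000 random lists of the same size and expression (grey bars). Tap root genes lie to the right in stem and capsule at day 5 (1.60 and 1.16) and to the left in capsule against stem (-2.12 and -2.09).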

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

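Of the tests in this part, the share over all comparisons and the thinning to equal depth were set out before their results were seen. The others were chosen after, though some use settings fixed beforehand, a minimum of 20 FPKM and the 3 scalings. Genes that went opposite ways at day 5 in stem and capsule numbered 87 (higher in stem) and 124 (lower in stem); with 1 library per group the difference between the tissues was not tested. PSUN8718.1 was the named gene among them, with log2 ratios of 8.70 in stem and -6.37 in capsule.

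For PSUN8718.1 the locus total, which adds the assembled models, was 764 FPKM in day 1 stem, 2423 in day 5 stem, 1007 in day 1 capsule and 1059 in day 5 capsule. Its log2 ratio was then 1.66 in stem and 0.07 in capsule, so the lower value in capsule may come from reads that StringTie gave to another model of the same locus. Over all 6 comparisons, 104 of 1380 differences of 16-fold or more (7.54%) were under 2-fold or turned in the locus total. There 1131 of the 1380 were still 16-fold or more, so this does not account for most of them. Between the 2 capsule libraries, 30 of 128 (23.4%) were under 2-fold or turned, the highest share of any comparison, and 77 were still 16-fold or more. Whether plants of day 5 use another transcript start or end at these loci was not tested.

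In day 5 stem most measured tap root genes were higher (median log2 ratio 1.60) and most of the 96 measured of 385 capsule genes lower (-2.75). Whether tap root RNA mixed into the library caused the rise cannot be told from these values. For the 93 measured tap root genes with 20 FPKM or more in tap root, the median gain was 42.6% of the tap root level. Of 104 tap root genes with 20 FPKM or more in tap root, 11 stayed under 10% of that level. Of the 93 measured in stem, 3 did. Measuring required 5 FPKM in a stem library, which tends to remove such genes, so this lower count does not weigh against the 11. Of these 93, 26 lay above both their tap root and their day 1 stem level, which a mixture of the 2 cannot give, but only 2 of them 2-fold above. Tap root of the day 5 plants was not sampled, so the levels that a mixture would add are not known. Thinning to equal depth, set out before, could hardly move medians of genes with this many fragments and decides nothing. A minimum of 20 FPKM was also applied both to the class tissue and to either stem library. The medians were then 1.72 (at most 84 tap root genes) and -3.49 (at most 51 capsule genes). This argues against the lower depth of day 1 stem as the cause. The 3 scalings shifted every stem log2 ratio by only 0.07 to 0.17, before 1 FPKM is added, so they could hardly move these medians. The lowest tap root median over them was 1.59, so scaling of that size does not account for the rise. Age, pollination and the change of plants differ together, as may the make-up of the stem piece, and all stay open.

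Loci with no annotated gene were not used in the comparisons but held reads in every library, and no control sample gives a level to set them against. Their share of all FPKM, assembled models included, was 15.6% in day 1 stem, 19.3% in day 5 stem, 18.3% in day 1 capsule, 23.1% in day 5 capsule, 15.5% in leaf, 20.3% in petal, 18.9% in stamen, 20.6% in tap root and 19.3% in fine root.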

How the results depend on the processing

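The mRNA model alone and the locus total were chosen after the data were examined; the other alternatives were fixed before. Of 169 recomputed counts, 102 stayed within 1.5 times the reported value and 67 did not. Of 631 values for single tissues, class medians and named genes, 490 stayed within 1.5-fold and 140 moved farther, most of them with the pseudocount. The 1 that turned was the median of petal genes between the capsule ages, from -0.089 to 0.046 in the locus total; the cause was not tested. The mRNA model alone, and leaving out the 100 most abundant genes, moved none of the counts by over 1.5 times. Without those genes, however, stem had 1740 genes higher at day 5 and 1432 lower. Leaving them out rescales each library and shifts every stem log2 ratio, before 1 FPKM is added, by 0.17. The median over measured genes was then 0.14, against -0.06 with FPKM as deposited. At the depth of day 1 stem, a 1 kb model under 0.281 FPKM cannot be told from 0. The alternatives for alkaloid coexpression and for functional list medians were not run, since no list had a member.

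A pseudocount of 5, which shrinks every ratio, left 609 tissue-enriched genes, 856 genes higher at day 5 in stem, 796 higher and 1080 lower in capsule, and 1080 higher in capsule than in stem at day 1. It left 163 genes higher and 250 lower at day 5 in both tissues, with 36 higher in stem alone and lower in capsule and 70 the opposite. A minimum of 20 FPKM, which tests fewer genes, left 873 tissue-enriched genes. Higher and lower were then 557 and 785 in stem by age, 517 and 620 in capsule by age, 641 and 712 in capsule against stem at day 1, 813 and 707 at day 5, 949 and 485 in fine against tap root, and 669 and 1177 in stamen against petal. The overlaps were 107 higher in both, 172 lower in both, 14 higher in stem and lower in capsule, and 49 the opposite.

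A minimum of 1 FPKM, which tests more genes, gave 2268 higher in stem by age, 2170 higher and 3235 lower in capsule by age, 3469 higher in capsule against stem at day 1, 3230 higher and 2908 lower at day 5, 3976 higher and 1781 lower in fine against tap root, and 5662 lower in stamen than petal. The overlaps were 501 higher in both, 686 lower in both, 242 higher in stem and lower in capsule, and 225 the opposite. The 4-fold rule, stricter by construction, gave 544 higher and 699 lower in stem, 469 and 668 in capsule, 738 and 665 in capsule against stem at day 1, 917 and 847 at day 5, 1347 and 485 in fine against tap root, and 201 and 1932 in stamen against petal. Its overlaps were 75 higher in both, 99 lower in both, 24 higher in stem and lower in capsule, and 28 the opposite.

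With TPM, under which more genes pass 5, there were 2024 higher in stem by age, 2930 lower in capsule by age, 2922 higher in capsule against stem at day 1, 2600 lower in capsule at day 5, 1705 lower in fine than tap root, and 193 higher in stem and lower in capsule. Median-of-ratios factors gave 1986 genes higher in stamen than petal, since they raise stamen, and 582 stamen-enriched genes in place of 75. The locus total, which tests more genes, gave 2886 higher in capsule than stem at day 5, 1857 lower in fine than tap root, 2026 higher and 6482 lower in stamen than petal, and 498 higher at day 5 in both tissues. Besides the 0.89 of stamen against petal, some scalings shifted every log2 ratio, taken before 1 FPKM is added, by over 0.1. TPM did so by -0.14 for capsule against stem at day 5 and by -0.13 for fine against tap root. Median-of-ratios did so by -0.21 for fine against tap root. Leaving out the top genes did so by 0.17 for stem by age, -0.24 for fine against tap root and 0.11 for stamen against petal.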

Other observations

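All tests in this part were chosen after the pattern was seen. For 4 of the 7 tissue classes, genes of the class lay next to each other on the chromosomes more often than in any of 1000 shuffles of the order of the 13983 expressed genes. Fine root genes formed 94 neighbouring pairs, against a mean of 23.9 and a highest value of 40 in the shuffles. Capsule genes formed 29 (mean 5.62, highest 14), leaf genes 17 (mean 6.71, highest 15) and stem genes 9 (mean 0.782, highest 5). For the other classes this did not hold: petal, stamen and tap root genes formed 3, 2 and 1 pairs, which 104, 65 and 394 of the shuffles reached. Shuffling single genes separates overlapping models and near-identical copies that share reads, and neither was checked for these pairs. No name or function was given to these genes.

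Of 13108 windows of 12 consecutive expressed genes, 2 that do not overlap had a mean pairwise Pearson's r over the 9 libraries above every shuffle (highest 0.819). One lay on unplaced scaffold 21 (13198745 to 13644095, mean r 0.852), with a median of 17.0 FPKM in fine root, 2.71 in tap root and at most 0.0106 elsewhere. Shared reads and overlapping models were not checked for this window. The other lay on chromosome 11 (127757902 to 128095498, mean r 0.837), with medians of 125 FPKM in day 1 stem, 148 in day 5 stem and 79.4 in tap root, and 0.396 to 26.7 in the other 6 libraries. Its most abundant gene, PS112647.1, chosen after its values were seen, had 622 and 692 FPKM in stem at day 1 and day 5. Not every gene of the window followed the medians. PS112649.1 had 1.74 FPKM in tap root and its highest value, 19.0 FPKM, in day 5 capsule. PS112643.1 had 131 FPKM in day 1 stem and 25.1 in day 5 stem.

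The chromosome 11 run may reflect shared control of neighbouring genes, which is a hypothesis that was not tested. Its mean r was reached in 0 of 1000 shuffles of the gene order, which argues against chance order. Reads shared among all of the genes would give them 1 ratio between libraries, but tap root to day 1 stem ratios ran from 0.179 to 3.22, with their counting intervals 16.6-fold apart; sharing between some pairs stays open. Of 11 neighbouring pairs, 0 overlapped or shared a StringTie locus, but the 12 genes lay in 11 loci: PS112643.1 and PS112653.1, which are not neighbours, shared one, and had ratios of 0.645 and 3.22. As background, the genome study of this cultivar described a cluster of alkaloid genes on chromosome 11; whether it is this run was not tested, since the identifiers are not paired with names.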
